A study of Arabidopsis thaliana with 6 samples.

How the data were processed

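RNA was labelled with biotin and hybridized to a 3-prime expression array, 1 array per sample, with 3 arrays of ka120 and 3 of WT. Plants grew at 22 degrees C with 12 h light and 12 h dark, per the labels' protocols. The deposited values are log2 levels, 1 per probe set, as their range of about 2 to 14 shows. The affy package is named per the submitters' processing notes; its version, the background correction, the normalization and the probe set summary are not given in the sources used here. Samples were grouped by the genotype in their titles.

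The table held 22810 probe sets, of which 64 array controls were left out of the tests. Names came from the platform annotation, updated through gene identifiers to the TAIR10.1 gene table. A single gene was named for 13513 probe sets (13436 matched the gene table), several genes for 503, and no gene for 8730, so many well-known genes are not analysed here. Of 147 genes with several probe sets, 0 had calls in opposite directions. A gene was represented by its brightest probe set.

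Differences were fitted on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block, no filter on dim probe sets), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists with at least 5 measured members. Of 537 planned list members 83 were measured: 5 lists had at least 5, 11 had 3 or 4, 9 had 1 or 2, and 6 had 0. A planned list of plastid genome genes had 0 measured members, and a planned list of ribosomal proteins chosen by description was not built, since the tables carry no descriptions. Members whose symbol differed from the reference name were matched by hand after the data had been seen.

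The design, lists, alternatives and naming rule were fixed before the data were examined. The rule named KA120 and its 5 nearest measured genes on each side, the 10 largest rises and 10 largest falls among genes whose 3 ka120 arrays all lay on 1 side of the 3 WT arrays, the 3 largest changes in each list called shifted, and 1 member of every other list; SNC1 and PR1 were to be named always. Alternatives were quantile normalization, median centring, removal of the dimmest 40% of probe sets, an intensity trend with a robust prior, array weights, a replicate block, the mean of a gene's probe sets, removal of probe sets shared between genes, each array left out, an estimated correlation and the rotation test fry, which asks whether a list differs from no change, while camera compares it with the other genes. Centring on hybridization controls, removal of a level-dependent offset in those controls, lists of 3 or 4 members and further families were added after the data had been seen.

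The fit was tested on simulated log2 values for 22746 probe sets, for ka120 against WT. It recovered 50.0% of probe sets changed by 0.5, 92.0% at 1 and 100.0% at 2 or 3 on the log2 scale. Of 22546 unchanged probe sets it called 3. Only 50 probe sets were changed at each size, against 8165 called in the data, so the adjusted threshold was stricter than in the data. The simulated noise was independent between probe sets, with no offset shared by the arrays of a group. These rates therefore do not carry over to the data.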

Results

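Transcript levels were measured on a 3-prime expression array in above-ground tissue of Arabidopsis thaliana, in the wild type (WT, accession Col-0) and in the ka120 mutant, with 3 biological replicates and 3 arrays per genotype. KA120 (AT3G08960) belongs to the importin-beta family of nuclear transport receptors. The sample records describe the tissue differently: the study design speaks of whole rosettes at 3 weeks, and the growth protocol and tissue label of mature leaves after 4 weeks. The number of arrays limits the precision of each value. Array medians lay between 4.63 and 4.79 on the log2 scale. Pairs of arrays of 1 genotype correlated across probe sets with r between 0.993 and 0.997, and pairs from different genotypes with r between 0.961 and 0.965. Genes are not independent replicates, so these coefficients describe the arrays only.

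The comparison of ka120 with WT asked which transcripts differ when this transport receptor is mutated. The probe set for KA120 itself gave 3.65, 4.12 and 4.17 on the ka120 arrays and 4.55, 4.34 and 4.42 on the WT arrays, a log2 difference of -0.45 (SE 0.14, limma adjusted p = 0.0222). These levels were below the array medians, and the site of the mutation relative to the probes is not given in the sources used here, so the probe set is a weak check of the genotype. The call was lost without ka120 replicate 1 (log2 difference -0.29, adjusted p = 0.0817) and without WT replicate 1 (-0.40, adjusted p = 0.0603). It was also lost after centring on the hybridization controls (-0.23, adjusted p = 0.216) and with the level-dependent control offset (-0.02, adjusted p = 0.917). Of the 10 nearest measured genes in the TAIR10.1 gene order, AT3G08920 fell by 1.61 on the log2 scale, LHCB4.2 by 0.68 and AT3G08890 by 0.59, while AT3G09010 rose by 1.69 and AT3G09020 by 0.84. AT3G08910, AT3G08930, AT3G08980, AT3G08990 and AT3G09000 did not pass the test, with log2 differences of 0.20, -0.02, 0.10, 0.24 and -0.08. The AT3G08890 call was lost with the level-dependent control offset (-0.15, adjusted p = 0.313), and AT3G08990 passed without WT replicate 2 (0.32, adjusted p = 0.0433).

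Among genes with a name, AT1G35710, a leucine-rich repeat receptor-like kinase, rose most, by 5.26 on the log2 scale, at 9.98 ± 0.12 in ka120 against 4.72 ± 0.50 in WT (log2, SD, n = 3 arrays each). CHI (AT2G43570), a chitinase, rose by 4.58, AT3G48640 by 3.96 and AT3G28540, an AAA-type ATPase, by 3.89. AT4G00700, AT5G59670, AT5G52760, AT1G10340, AT1G43910 and AT5G55450 completed the 10 largest rises, by between 3.35 and 3.77 on the log2 scale. The WT means of these 10 genes lay between percentiles 19.9 (AT3G48640) and 60.7 (AT3G28540) of all probe sets, and the dim ones were not shown to exceed background, so the differences are not given as folds. The 2 largest rises among probe sets unnamed here were 6.78 and 6.28 on the log2 scale.

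The largest fall was in AT1G08360, which encodes a protein of the large cytosolic ribosomal subunit. Its level was 9.88 ± 0.10 in WT and 3.42 ± 0.06 in ka120 (log2, SD, n = 3 arrays each), a log2 difference of -6.46. AT5G59130, a subtilase, fell by 3.57 on the log2 scale. COR15A and COR15B, which encode cold-induced chloroplast proteins, fell by 3.07 and 2.54. AT5G44530, AT5G48490, AT1G73600, AT3G46370, AT4G25780 and AT5G66740 gave log2 differences between -2.85 and -2.45. The ka120 means of these 10 genes lay between percentiles 15.0 (COR15A) and 91.4 (AT5G48490) of all probe sets, with AT1G08360 at 30.0 and COR15B at 31.2; the dim ones were not shown to exceed background, so these differences are not given as folds either. Adjusted p-values of these 20 named genes lay between 3.13e-11 and 3.46e-06 (limma). The 2 largest falls among unnamed probe sets were -4.34 and -3.70 on the log2 scale.

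**Figure D1:**
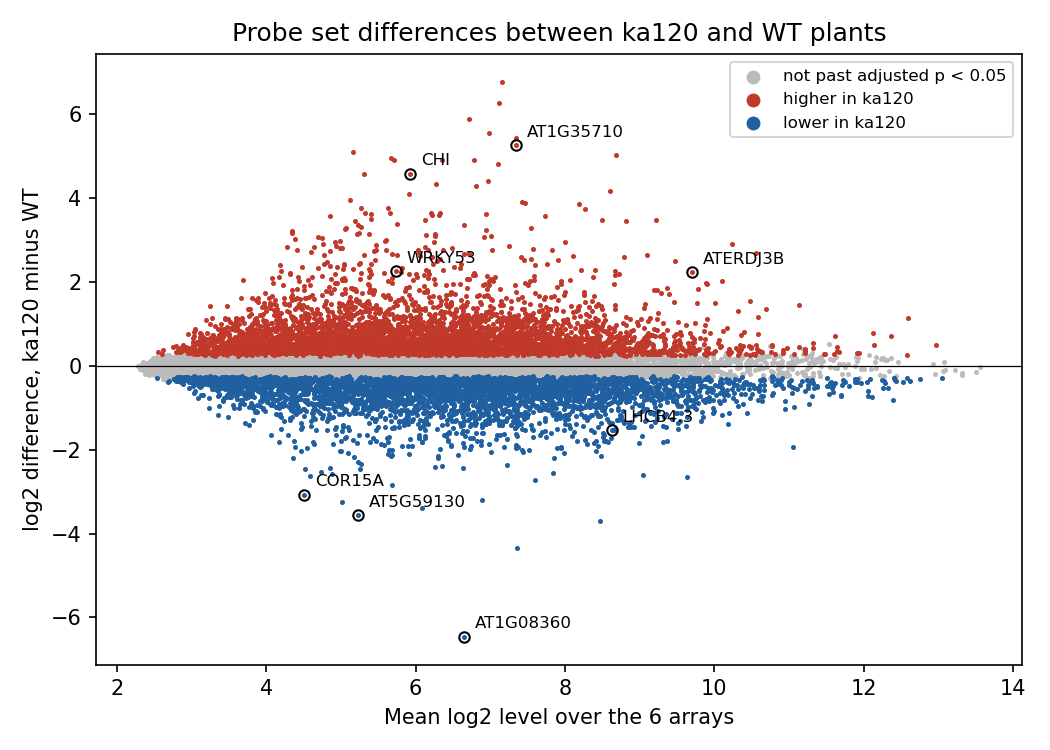
Log2 difference (ka120 minus WT) of each probe set against its mean log2 level over the 6 arrays; red and blue points passed adjusted p under 0.05 as higher or lower in ka120, grey points did not, and 8 named genes are circled. AT1G35710 lies at 5.26 and AT1G08360 at -6.46.

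Across the array, 8165 of 22746 probe sets passed an adjusted p of 0.05, 4405 higher and 3760 lower in ka120 (limma, Benjamini-Hochberg). At least 2-fold differences numbered 874 higher and 598 lower, and 665 higher and 828 lower after centring each array on its median. Counted as genes, 4395 of 13355 passed, 2331 higher and 2064 lower. Of the probe sets with no gene named 41.1% passed, against 32.7% of those with a name, so the named genes do not stand for the whole array. The balance of higher and lower calls depended on the scaling: 54.0% of calls were higher with the deposited values, 34.7% after centring each array on its median, 80.3% after centring on the hybridization controls and 91.8% after removing an offset that varied with level in those controls. Adjusted p-values under the control-based scalings are too small here and below, as noise of the controls, shared by all probe sets, raised the limma prior degrees of freedom from 6.65 to 15.77 and 41.79. The level-dependent offset applied the shift of the dimmest hybridization control, BioB, to all probe sets below it. A level of 7.50, near that of BioB, was at percentile 85.0 in WT, so most probe sets took this 1 shift. Small differences have no settled direction in these arrays.

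Of the 5 gene lists with enough measured members, the photosynthetic light reactions were the 1 list called shifted. All 8 measured members fell, also when adjusted over the list alone, with a median log2 difference of -0.42 (camera adjusted p = 0.000216; adjusted p = 0.104 with an estimated correlation). The LHCB4.3 antenna protein of photosystem II fell by 1.54, the PSAN subunit of photosystem I by 0.82 and LHCB4.2 by 0.68 on the log2 scale. The list's median was negative under each scaling tried, between -0.54 and -0.19, while the number of members that fell ranged from 3 to 8. Of the 3 measured Calvin cycle genes 2 fell, SBPASE by 0.62 and PRK by 0.30, and RCA gave -0.09; 1 member fell under quantile normalization and under either control-based scaling.

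In the planned list of nucleotide-binding leucine-rich repeat receptors, 3 of 5 measured members rose and 1 fell. The same counts held when adjusted over the list alone. TN13, a listed member without leucine-rich repeats, rose by 1.43, CSA1 by 1.12 and SOC3 by 0.61, and AT4G16920 fell by 0.41. Of 6 measured genes of pattern-triggered immunity 2 rose, the kinase BIK1 by 1.37 and the ubiquitin ligase PUB24 by 1.25, and the other 4 lay between -0.03 and 0.14; adjusted over the list alone the count was also 2. Of 6 measured nuclear pore genes 3 rose, also when adjusted over the list alone: NUP98B by 0.74, NUP155 by 0.54 and NUP85 by 0.33. NUP98B, SOC3 and AT4G16920 were dim, at percentiles 19.5, 28.2 and 26.6 in WT and 38.7, 40.5 and 12.8 in ka120. Their levels were not shown to exceed background. These 3 lists missed the threshold at a camera adjusted p of 0.0515 each (0.226, 0.226 and 0.318 with an estimated correlation). Over the alternatives the nucleotide-binding receptors passed camera in 4 of 17 (adjusted p between 0.0394 and 0.226), pattern-triggered immunity in 3 of 17 (0.0418 to 0.226) and the nuclear pore in 6 of 18 (0.0234 to 0.329). Each passed with array weights and without ka120 replicate 2 (0.0415, 0.0418 and 0.0234), the receptors and the nuclear pore also after median centring (0.0394 each) and without WT replicate 2 (0.0484 each), and pattern-triggered immunity and the nuclear pore without WT replicate 1 (0.0458 and 0.0347). The nuclear pore list passed, at 0.0351, when the member SEH1H was left out; its match to the planned name SEH1 was made after list values had been seen. Of the 7 measured nuclear transport receptors other than KA120 1 rose, IPO8 by 0.53, also when adjusted over the list alone (camera adjusted p = 0.634). How many members rose depended on the scaling. Centring on the hybridization controls and the level-dependent offset gave 4 and 5 rising transport receptors, 5 and 6 nuclear pore genes, and 3 and 6 genes of pattern-triggered immunity, and AT4G16920 was not called lower under either. Quantile normalization and median centring gave 1 rising and 2 falling transport receptors each (median -0.05 under both, against 0.07 as deposited), 3 and 2 rising nuclear pore genes, and 2 and 2 rising genes of pattern-triggered immunity, whose median was -0.03 after median centring.

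The lists with 3 or 4 measured members were tested after the data had been seen. Endoplasmic reticulum folding genes rose together, 4 of 4 and also adjusted over the list alone: the chaperone ATERDJ3B by 2.24, the calreticulin CRT1b by 1.97, and the unfolded protein response factors BZIP60 by 1.04 and BZIP28 by 0.70 (camera adjusted p = 3.84e-05; adjusted p = 0.102 with an estimated correlation). Cold and abscisic acid response genes fell, 4 of 4 and also adjusted over the list alone, COR15A by 3.07, COR15B by 2.54, COR47 by 1.21 and LTI30 by 0.39 (camera adjusted p = 0.000325, and 0.127 with an estimated correlation). Under either control-based scaling 3 of them fell. LTI30 was dim, at percentiles 26.7 in WT and 13.9 in ka120, and its levels were not shown to exceed background. Of 3 measured genes in the list of salicylic and pipecolic acid synthesis and its regulators 2 rose, also adjusted over the list alone, the EDS1 partner SAG101 by 1.62 and the pipecolic acid synthesis enzyme SARD4 by 1.27 (adjusted p = 0.00949; 0.336 with an estimated correlation). Of 3 salicylic acid response genes 2 rose, also adjusted over the list alone, WRKY53 by 2.26 and the glutaredoxin GRX480 by 1.103 on the log2 scale (adjusted p = 0.0437; 0.336 with an estimated correlation). The other 7 lists of this size did not pass, at adjusted p between 0.0623 and 0.706. SNC1 and PR1 are not analysed here.

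**Figure D2:**
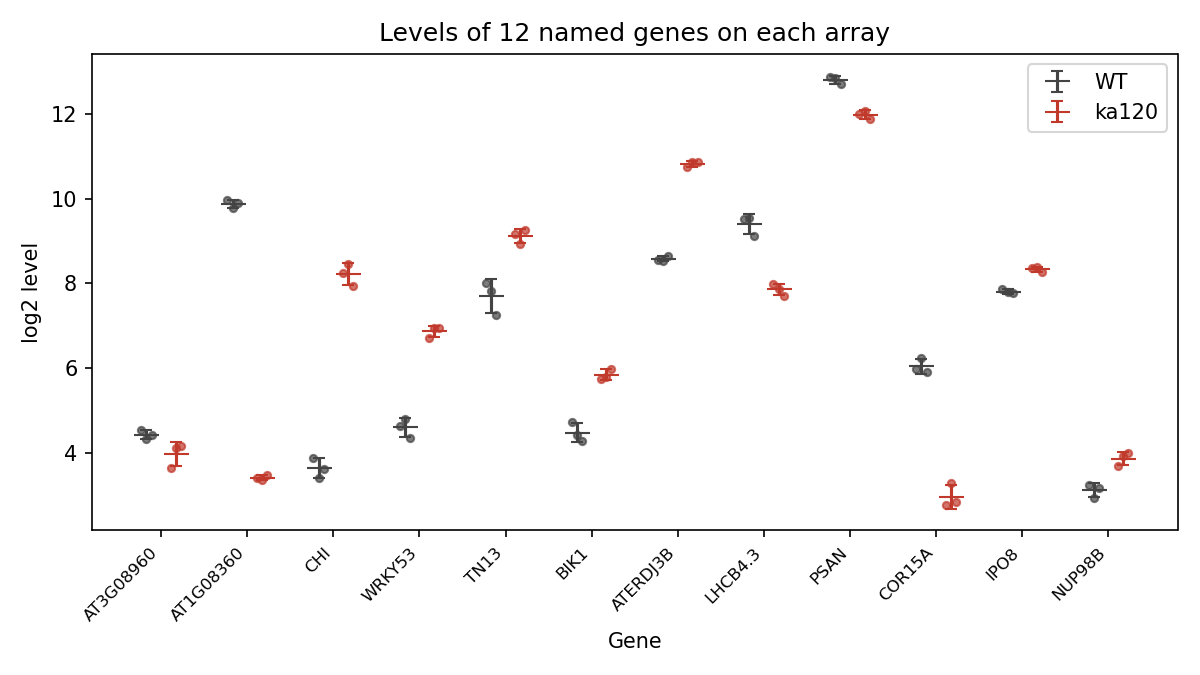
Log2 levels of 12 named genes on the 3 WT arrays (grey) and the 3 ka120 arrays (red); points are arrays, horizontal marks the means and bars the SD. AT1G08360 falls from 9.88 to 3.42 and ATERDJ3B rises from 8.58 to 10.8.

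In other lists with 3 or 4 members, BCAT4 of aliphatic glucosinolate synthesis rose by 1.35, EXO of cell expansion by 1.74, PRL of cell division by 0.84 and DFR of anthocyanin synthesis by 1.26. Of the 4 measured cell expansion genes 1 other was called, EXPA8, named after its values had been seen, which fell by 0.58 (adjusted p = 0.00224). The DFR call was lost with an intensity trend and robust prior (adjusted p = 0.0525). SPCH, a stomatal lineage gene in the guard cell list, gave -0.21 and did not pass. Among commonly used reference genes GAPC2 fell by 0.25 (adjusted p = 0.0421), a call lost in each fit that left out 1 array, with a replicate block, under quantile normalization and under either control-based scaling. In lists with 1 or 2 measured members, JMT fell by 0.46, SAG29 by 0.71 and TRY by 1.07, and GI rose by 0.65 and PYE by 0.56. PDF1.2 gave 0.10, EXPA18 -0.31, CLV3 -0.10 and ATHSP22.0 -0.04 without passing the test. JMT lost its call under either control-based scaling and SAG29 with the level-dependent offset (-0.28, adjusted p = 0.0868), while PDF1.2 passed as higher under both (0.33 and 0.54, adjusted p = 0.0303 and 0.000689). EXPA18 passed as lower after median centring (-0.43, adjusted p = 0.024), with a replicate block (-0.31, adjusted p = 0.0371) and without WT replicate 3 (-0.41, adjusted p = 0.0375).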

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

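The tests of the control transcripts against each other and both tests of the lower calls alone were chosen after the result was seen. Array control probe sets, which were left out of the tests of genes, differed between the genotypes: 15 of 64 passed an adjusted p of 0.05 (limma), 12 lower and 3 higher in ka120. With all 3 ka120 arrays on 1 side of the 3 WT arrays and at least 1 probe set past the threshold, the hybridization control BioB differed by -0.44 (SE 0.07), BioC by -0.26 and the polyadenylated control Lys by -0.20, while 25S rRNA differed by 0.41, GAPDH by 0.17 and ubiquitin by 0.16 (ka120 minus WT, log2). BioD (-0.13) and the polyadenylated control Dap (-0.29) were separated in the same way with 0 probe sets past the threshold. These values are means over the probe sets of each control. For GAPDH they ran from 0.003 (middle) to 0.42 (3-prime), and for ubiquitin from 0.02 (middle) to 0.27 (5-prime). Actin, with a mean of -0.006, gave 0.112 and 0.161 in 3-prime probe sets and -0.195 and -0.132 in 5-prime ones. A difference along the transcripts was not tested.

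The hybridization controls are added in known amounts, yet BioB and BioC were lower in ka120 and the brightest, Cre, differed by 0.03 (SE 0.05). A single factor per array that acts alike at all levels would move BioB and BioD alike. Their shifts differed by -0.31 (SE 0.05), which argues against such a factor. A factor whose effect shrinks at bright levels is not covered by this comparison. An offset that varies with level, which between-array normalization could leave, stays open.

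After removing such an offset 70.9% of all calls were kept with their direction, above the 50% set beforehand as evidence against it, but that bound was wrong: the removal moved 4402 of 4405 higher calls further up, so they could hardly be lost, and 70.9% decides nothing. Of the lower calls 1382 of 3760, or 36.8%, were kept; with the standard errors of the deposited values, 695 fell beyond the offset at their level plus 2 SE of the BioB shift, which argues against it as the cause of every lower call. For the 2378 lower calls that were lost (median -0.44, SD 0.13, before and -0.03, SD 0.13, after) the offset and lower transcript levels cannot be told apart. Below the level of BioB its shift of -0.44 was carried on. By the mean over their probe sets the polyadenylated controls shifted less: Dap by -0.29 (SE 0.13), Phe by -0.23 (SE 0.10), Lys by -0.20 (SE 0.05), Thr by -0.09 (SE 0.14) and Trp by -0.06 (SE 0.06). Single probe sets ran from -0.47 to -0.22 for Dap, -0.44 to 0.04 for Phe and -0.37 to -0.05 for Lys. The means mix dim 5-prime probe sets, not shown to exceed background, with brighter ones, and the 3-prime Dap probe sets lay above BioB. The removal may be too strong for dim probe sets, but these means do not settle it.

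The breadth of the difference was set against other groupings of the arrays. The real grouping called 8165 probe sets, 1 of 10 splits called as many, and the highest of the other splits called 0. With 10 splits a share under 0.05 cannot be reached.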

How the results depend on the processing

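The control-based scalings, the ordinary t test and the omission of later name matches were chosen after the data had been seen. Counts of calls stayed within 1.5 times in the alternatives fixed beforehand except for lower calls after median centring (6235), which subtracts the higher ka120 array medians and so shifts differences down. Centring on hybridization controls gave 7971 higher and 1955 lower calls (1428 and 332 at 2-fold), and the level-dependent offset gave 16857 calls, 15475 higher and 1382 lower, with 2460 at 2-fold (2239 and 221) and 9940 named genes; these follow from the added offset. Control noise is shared by all probe sets, so the limma prior rose from 6.65 degrees of freedom to 15.77 and 41.79, and adjusted p-values under these scalings are too small; an ordinary t test called 5933 higher and 1261 lower, and 11550 higher and 978 lower (3073 and 2745 as deposited). The median difference over all probe sets was -0.02 as deposited, -0.15 after median centring, 0.21 on hybridization controls and 0.41 with the level-dependent offset. Under the last, AT3G08930 (0.38), AT3G09000 (0.36), ATHSP22.0 (0.40) and CLV3 (0.33), not called before, were called higher; so were AT3G08910 (0.64), AT3G08980 (0.54), AT3G08990 (0.68) and PDF1.2 (0.54), which also passed on hybridization controls (0.42, 0.33, 0.47 and 0.33).

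The number of lists called shifted, 1, was 0 with an estimated correlation, 3 after median centring, 4 with array weights, 2 without the later name matches, and between 1 and 4 with each array left out (4 without ka120 replicate 2, 3 without WT replicate 1 and 3 without WT replicate 2); the cause was not tested. The rotation test, which asks about a shift up or down from no change and not relative to other genes, passed 4 lists. The photosynthetic list passed camera in 17 of 18 alternatives, with adjusted p between 9.25e-10 and 0.104. KA120 lost its call under both control-based scalings (-0.23 and -0.02).

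Deviations of same-numbered arrays correlated at -0.01, -0.19 and 0.13, within the range of the other pairs across genotypes (-0.28 to 0.26). With 3 arrays per genotype these values neither show nor exclude a pairing by replicate number. With a replicate block 7868 probe sets were called, and 1 list. The pseudocount alternative was not run, since the values are on a log scale. Levels near background were not marked in the values used here, which limits small differences in dim probe sets.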

Other observations

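The tests of all families below, and those of the neighbours and the level of AT1G08360, were chosen after the data had been seen. Families listed by locus code were tested as sets, and 0 of 5 passed with an estimated correlation. Of 22 measured genes for entry into the secretory pathway 12 rose and 1 fell (camera adjusted p = 0.000141, and 0.0741 with an estimated correlation). Among those that rose were AT3G60540 by 2.17 and AT1G29310 by 1.03. After median centring 9 rose and 2 fell, with a median of 0.18 against 0.31 as deposited. Under the control-based scalings 16 and 20 rose. Of 9 genes for plastid ribosomal proteins 7 fell, AT5G24490 by 0.82 and AT5G65220 by 0.51 (adjusted p = 0.000436; 0.171 with an estimated correlation), though 1 and 2 fell under the control-based scalings. Of 76 genes with a TIR domain, found in many immune receptors, 25 rose and 2 fell, AT1G66090 by 2.31 and AT5G58120 by 2.06 among those that rose (adjusted p = 0.000436; 0.171 with an estimated correlation); their median was 0.07 and turned to -0.05 after median centring, and 37 and 65 rose under the control-based scalings. Of 107 genes for cytosolic ribosomal proteins 25 rose and 2 fell (adjusted p = 0.000436; 0.171 with an estimated correlation), and after median centring 11 rose and 11 fell, against 72 and 71 that rose under the control-based scalings. Of 34 malectin-like receptor kinases 6 rose and 1 fell (adjusted p = 0.327), and 4 rose and 4 fell after median centring, against 10 and 30 that rose under the control-based scalings. Over all genes measured 2331 of 13355 rose and 2064 fell with the deposited values, so a count of calls alone does not set a family apart.

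All 37 families of named genes sharing a symbol stem, with at least 7 measured members, were also tested. With the preset correlation 2 passed: UBP ubiquitin proteases, of which 9 of 12 rose (median 0.40, adjusted p = 0.00178), and UGT glycosyltransferases, of which 16 of 47 fell and 4 rose (median -0.15, adjusted p = 0.045). With an estimated correlation 0 of the 37 passed, at adjusted p = 0.541 and 0.565 for these families.

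AT1G08360 was bright on the WT arrays and lay at percentile 30.0 of all probe sets on the ka120 arrays. Loss of a chromosome segment holding most of the 10 nearest measured genes was set against their median difference of -0.075 (SE of the median over genes 0.20). AT1G08310, AT1G08340 and AT1G08590 were dim in WT (percentiles 25.5, 22.9 and 34.2) and could hardly fall further, so the median alone cannot decide. A segment holding most of the 10 would include the nearest upstream gene, AT1G08350. It gave 0.10, at 5.65 (SD 0.11) in ka120, which argues against such a loss. The nearest measured genes on the downstream side, AT1G08390 and CPNIFS, fell by 1.41 and 0.50, to percentiles 54.2 and 72.9 in ka120. CPNIFS stayed at 6.53 (SD 0.09) there, against 3.42 (SD 0.06) for AT1G08360, which argues against a shorter loss that covers both neighbours. Their background is not known here, so a loss that reaches AT1G08390 but not CPNIFS stays open. A general fall of cytosolic ribosomal transcripts is argued against by a median of 0.16 over the other 106 such genes (SE of the median over genes 0.03). Genes are not independent replicates, so these SE values over genes may understate the uncertainty. With AT1G08360 included, the family median was 0.03 after median centring and 0.38 under either control-based scaling. A sequence change or insertion in this gene or under its probes in the ka120 line may give the same low level, and percentile 30.0 does not separate that from lost transcription.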
